A study of Homo sapiens with 6 samples.

How the data were processed

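Kinome peptide arrays were analysed from macrophage-like THP-1 cells in 3 groups of 2 arrays: unstimulated, IL-17A/F and IL-32γ, each cytokine at 20 ng/ml for 15 min. Per the labels, each group has biological replicates 1 and 2, and the series text speaks of independent experiments. Arrays of one replicate number are called an experiment here, although no label states that they were run together. The 2 arrays per group limit the precision of each value.

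Per the file headers, the deposited scanner tables give the mean foreground and mean local background intensity of each spot in the green channel, 900 spots per array, not background subtracted. Scanner settings are not given in the sources used here. The highest foreground of an array lay between 57693 and 64389 units, and median background between 13397.5 and 21585.5 units. The authors' deposited value table holds a ratio per peptide, and no label states how it was made. Set against the scanner values of each array, every column correlated with the mean of foreground minus background over 3 spots at 1.00, divided by the array's 80th percentile of those means and held at a floor of 0.01. Between 84 and 105 peptides per array sit at that floor. The column medians were 0.466 and 0.509 for the unstimulated arrays, 0.553 and 0.485 for IL-17A/F and 0.476 and 0.490 for IL-32γ. The values are linear and not centred, and no direction is involved. Here the authors' values serve as an alternative and for display.

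Intensities were background corrected with normexp (offset 50), quantile normalized between arrays on spots, put on the log2 scale and averaged over the 3 spots of a peptide. Fold changes were fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes) over all 6 arrays with group as the only term, and p-values were adjusted by Benjamini and Hochberg over 300 peptides. All p-values for peptides are two-sided and from limma. The study's cutoffs, from the series text, are a fold above 1.5 and an unadjusted p below 0.06. This model compresses differences: the slope of the log2 values on those of the authors' table was 0.219. Normalization assumes that most peptides do not change, so a shift common to all would be removed. A peptide below background on both arrays of both groups gets no fold and is left out of the counts of higher and lower peptides, though it stays in the list tests.

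Lists of pathway proteins were fixed before the data were examined and tested with camera at a preset correlation of 0.01, beside camera with an estimated correlation and fry. For fry, which tests whether a list's peptides move one way on balance, 0 lists in any comparison had an unadjusted p below 0.05. The 11 lists tested hold 230 peptides. The signs of a list's median and mean differed in 6 lists for IL-32γ against unstimulated cells, 5 for IL-17A/F and 3 between cytokines; those of its median and camera test differed in 4, 2 and 1. The files name 204 proteins, of which 200 were matched by hand to gene symbols. The other 4 stay under the file's name, among them p40phox and FRS3, whose database identifiers in the files belong to other proteins. For 7 peptides the files give no site, and Akt1 without a site and PLCB1 S887 each appear as 2 peptides. Unused columns of per-sample values numbered 0.

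Peptides were named by a rule fixed before the data were examined. It took all peptides past the adjusted p, then those past the study's cutoffs with the same sign in both same-numbered pairs, and where fewer than 10 remained, the 10 with the largest moderated t in each direction (6 in each direction between cytokines). All peptides of p300 and DAPK1 were added. Since 0 passed, the named peptides are those with the largest t. Some peptides that the rule takes are not reported here. Other peptides named in the text were chosen after their values were seen.

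The steps were tested on simulated data. For IL-32γ against unstimulated cells, 60 of 300 peptides were changed in 100 runs, 20 at each of log2 0.3, 0.6 and 1.2, on the normalized scale. The share recovered was 37.6%, 91.9% and 99.7%, with 2.07 false calls per run. Noise in these runs was drawn independently for each array. On the normalized scale, halving the net signal of peptides moved them by a median log2 of -0.26, a smaller step than the smallest size tested. The shares therefore do not give the chance of finding a halved signal. Correlations of fold changes were compared with 1000 simulations, and counts with 200. Their noise, too, was drawn independently for each peptide and array. Their ranges may be too narrow where arrays or peptides share deviations. Alternatives covered background correction, normalization, the offset, dim peptides, spot averaging, the variance model, the groups in the fit, the replicate block, the authors' values and each array left out.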

Results

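Phosphorylation of 300 peptides was measured with kinome peptide arrays in macrophage-like THP-1 cells, a human monocytic leukaemia line differentiated with a phorbol ester. The cells were left unstimulated or were given recombinant IL-32γ or IL-17A/F at 20 ng/ml for 15 min. Each group had 2 arrays from separate biological experiments, 6 arrays in all, and each peptide was printed at 3 spots per array. A peptide carries a short stretch of a named protein around a known phosphorylation site, given by its residue (S, T or Y for serine, threonine or tyrosine) and position. Staining with a phosphoprotein dye was read as green fluorescence. Of the 300 peptides, 189 were brighter than their local background on all 6 arrays, 74 on none and 37 on some of them. Between 26.1% and 35.4% of the spots of an array were not above local background.

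Of the peptides of tyrosine kinases and their adaptors, 29 of 38 were above background on all 6 arrays, and of the JAK-STAT and interferon peptides 23 of 30. Of the transcription factor and co-activator peptides, 10 of 28 were above background on all 6 arrays and 13 on none. Among the 27 peptides of the path from TLR, IL-1 and IL-17 receptors to NF-κB, 15 were above background on all arrays and 10 on none. The peptide of RuBisCO was below background on all 6 arrays, and that of bacterial flgE had a net signal between 37.7 and 1232 units. The 80th percentile of net peptide signal was 13544 ± 1057 units in unstimulated cells, 8745 ± 862 after IL-17A/F and 10925 ± 1254 after IL-32γ (SD, n = 2). With 2 arrays against 2, the smallest p that a two-sided exact permutation test allows is 0.333.

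**Figure D1:**
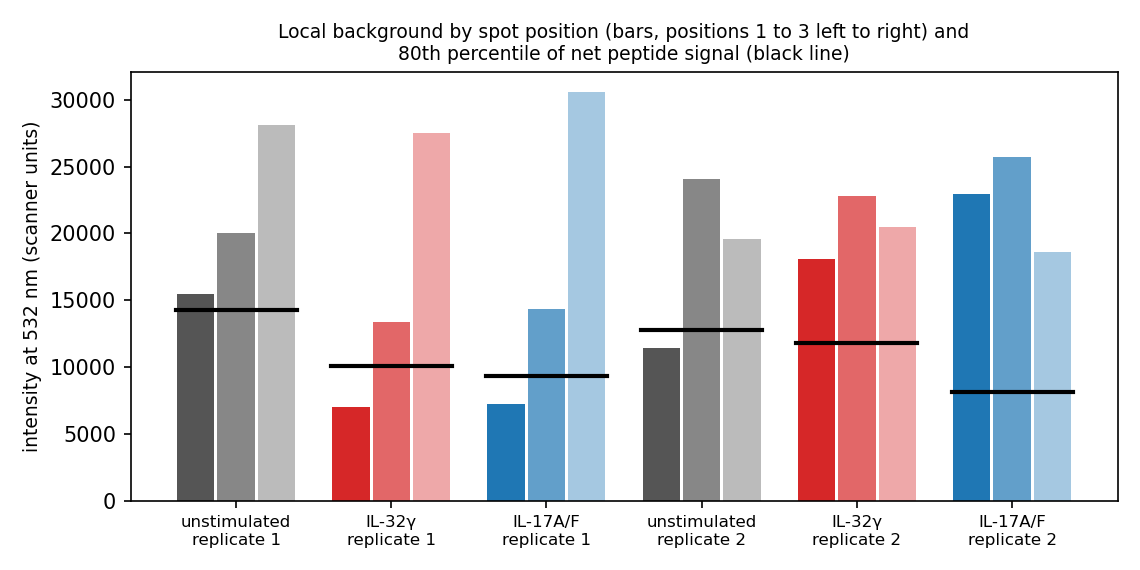
Bars give the median local background in scanner units at the 3 spot positions of each of the 6 arrays, and black lines the 80th percentile of net peptide signal. Net signal was 9354 and 8135 units on the IL-17A/F arrays and 14292 and 12797 on the unstimulated arrays; background differed between spot positions by 1.26 to 4.24 times within an array.

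The first comparison asked which peptides differed in signal between cells given IL-32γ and unstimulated cells. Values are signals of printed peptides named by their site, not readings of that site on the cells' own proteins. The largest differences relative to their error were lower values at peptides of 2 NF-κB subunits. NFkB-p65 S536 (RELA), a site in the transactivation domain that IκB kinases phosphorylate, had a log2 difference of -0.58 (SE 0.15, 95% CI -0.95 to -0.22). NFkB-p105 S337 (NFKB1), in the precursor of the p50 subunit, had a log2 difference of -0.32 (SE 0.081, 95% CI -0.52 to -0.12). IKK-beta Y199 (IKBKB), in the kinase that marks IκB proteins for degradation, had a log2 difference of 0.32 (SE 0.11, 95% CI 0.04 to 0.60). The IKK-beta Y199 difference was 0.097 and 0.54 in the 2 replicates and ranged from 0.20 to 0.43 as each array was left out. None of the 300 peptides passed limma's adjusted p, so these are values and not called changes.

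On the authors' relative scale, where 1 is the array's 80th percentile, NFkB-p65 S536 read 1.19 and 1.35 after IL-32γ against 1.91 and 1.86 in unstimulated cells. NFkB-p105 S337 read 0.111 and 0.0926 against 0.511 and 0.766. IKK-beta Y199 read 1.17 and 1.37 against 1.04 and 0.817. Other peptides of these proteins had smaller differences or no signal. NFkB-p65 S311 had a log2 difference of -0.17 with a CI from -0.81 to 0.47, and NFkB-p65 S276 and NFkB-p105 S907 were below background on all arrays. The IkB-alpha peptide with the serine pair whose phosphorylation precedes degradation of the inhibitor had a log2 difference of 0.01 with a CI from -0.24 to 0.26. TBK1 S172, in the activation loop of a kinase upstream of interferon genes, had a log2 difference of 0.18. Of the 27 peptides on the TLR, IL-1, IL-17 receptor and NF-κB list, 17 were above background on at least 1 array of the groups compared (measured, here and for the other lists). Of these 8 were higher and 9 lower, and 0 passed limma's adjusted p. Adjusted over the list alone, 0 passed and the smallest adjusted p from limma was 0.117. The list as a whole gave a camera p of 0.730, and a p of 0.770 with an estimated correlation; over all 27 peptides its mean difference was -0.03 and its median 0.0012.

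**Figure D2:**
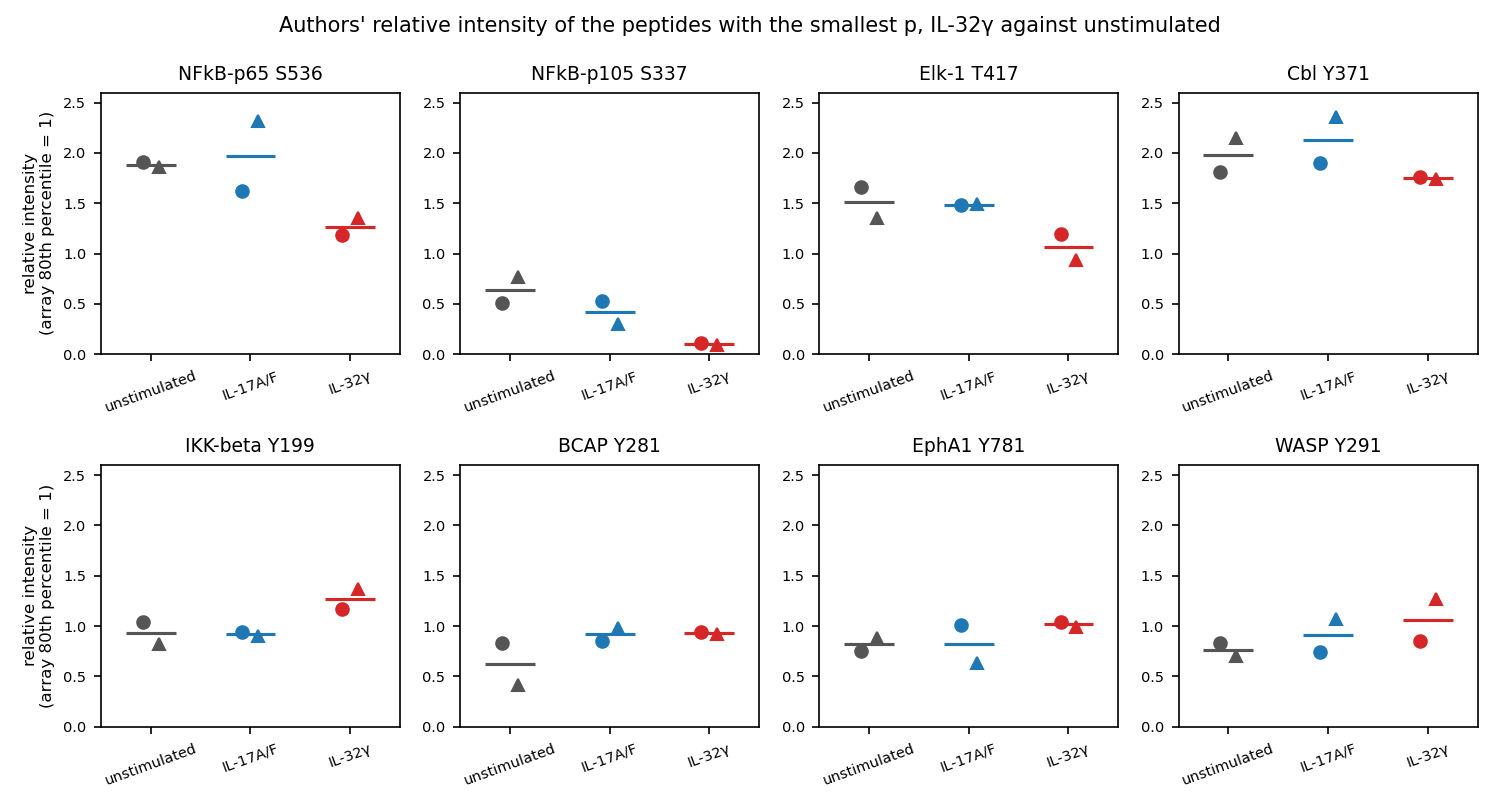
Points give the authors' relative intensity (array 80th percentile = 1) of 8 peptides, circles for replicate 1 and triangles for replicate 2, with bars at the mean of 2 arrays. NFkB-p65 S536 reads 1.19 and 1.35 after IL-32γ against 1.91 and 1.86 in unstimulated cells; none of the 8 peptides passed the test over all 300.

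Among transcription factors, Elk-1 T417 (ELK1), of an ETS factor that ERK kinases phosphorylate, had a log2 difference of -0.39 (SE 0.15). Jun S63, an AP-1 subunit site that JNK phosphorylates, was below background on all arrays. The co-activator list counted 7 higher and 8 lower of 15 measured peptides, with 13 others below background, 0 past the test and a camera p of 0.991. In the JAK-STAT and interferon list, STAT4 Y693 had a log2 difference of -0.25 (SE 0.15). IL2RB Y536 and IL2RB Y364, in the β chain shared by the IL-2 and IL-15 receptors, had differences of 0.25 (SE 0.16) and 0.17 (SE 0.11). In the 2 replicates IL2RB Y536 gave -0.069 and 0.58, and IL2RB Y364 gave 0.0034 and 0.33. That list counted 12 higher and 12 lower of 24 measured, with 0 past the test. In the list of tyrosine kinases and adaptors, Pyk2 Y402 (PTK2B), the autophosphorylation site of a focal adhesion kinase, had a difference of 0.37 (SE 0.19), which ranged from 0.073 to 0.68 as each array was left out and was 0.04 and 0.69 in the 2 replicates. Cbl Y371, in an E3 ubiquitin ligase that targets receptor kinases, had a difference of -0.23 (SE 0.096). Kit S821 was below background on all arrays. That list counted 20 higher and 15 lower of 35 measured, with 0 past the test.

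The MAP kinase list counted 10 higher and 16 lower of 26 measured peptides, with 0 past the test; ERK1 T202/4 had a log2 difference of 0.10. WASP Y291 (WAS), which drives actin branching in blood cells, had a difference of 0.28 (SE 0.14), in a cytoskeleton list with 3 higher and 4 lower of 7 measured. The WASP Y291 difference was 0.049 and 0.51 in the 2 replicates and ranged from 0.11 to 0.42 as each array was left out. PKG1 T58 (PRKG1), of the cGMP-dependent kinase, had a difference of -0.16 (SE 0.076), in a PKC, PKA and calcium list with 3 higher of 10 measured. The TNF receptor and apoptosis list counted 5 higher of 13 measured. The PI3K and AKT list counted 6 higher of 10 measured, the cell cycle list 4 of 5, and the lymphocyte receptor list, which holds markers of other cell types, 2 of 6. Outside the lists, BCAP Y281 (PIK3AP1), an adaptor that recruits PI3K, had a difference of 0.24 (SE 0.11), EphA1 Y781 of 0.22 (SE 0.11) and CD45 S999/02/03 (PTPRC), a receptor phosphatase of blood cells, of 0.20 (SE 0.12). GCAP2 S200 (GUCA1B), a guanylate cyclase activator, had a difference of -0.20 (SE 0.10). IKK-gamma S43 (IKBKG) was below background on all arrays.

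The co-activator p300 (EP300) and the death-associated kinase DAPK1 are known from the published study of these cells, which chose them on these samples, so they are not independent evidence. p300 S1834 had a log2 difference of 0.15 (SE 0.12, 95% CI -0.15 to 0.46) after IL-32γ and 0.15 (SE 0.12, 95% CI -0.16 to 0.45) after IL-17A/F, above background on 5 of the 6 arrays. These ranged from 0.0069 to 0.30 and from 0.0054 to 0.29 as each array was left out; on the authors' scale the unstimulated arrays read 0.326 and the floor of 0.01. DAPK1 S308 had differences of 0.05 (SE 0.11) and 0.10 (SE 0.11). p300 S893 and DAPK1 S735 were below background on all 6 arrays.

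In limma, 0 of 300 peptides passed an adjusted p of 0.05 between IL-32γ and unstimulated cells, and the smallest adjusted p was 0.991. At an unadjusted p of 0.05 there were 4 peptides where chance gives 15, and 8 with the replicate number as a term in the model. Counts this far under chance leave open that the p-values of the main model are too large. They do not show that nothing changed. By the study's cutoffs, fold change above 1.5 and p below 0.06, 0 passed; 5 peptides had such a p where chance gives 18. NFkB-p65 S536 missed that fold cutoff narrowly, at 1.498-fold, and passed both cutoffs in 10 of 26 settings, among them plain background subtraction and 4 that left out a single array. The background model compresses folds, since doubling the net signal of 30 peptides gave a log2 change of 0.52 and halving that of 30 others one of -0.26. On the authors' own relative values, 3 peptides passed the study's cutoffs, all lower after IL-32γ: NFkB-p105 S337, PKG1 T58 and CTNNB1 S675 (β-catenin). The last read 0.0138 and 0.0179 in unstimulated cells and the floor of 0.01 on the other 4 arrays, and with 0.1 added to all values NFkB-p105 S337 alone passed. In none of the 11 lists did camera in limma give an adjusted p below 0.05. Without background correction it did for the NF-κB list (lower, adjusted p = 0.0053) and the tyrosine kinase list (higher, adjusted p = 0.0495).

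The second comparison set cells given IL-17A/F against unstimulated cells. MKP-1 S296 (DUSP1), in a phosphatase that switches off MAP kinases, had the smallest unadjusted p, with a log2 difference of -0.22 (SE 0.093, 95% CI -0.45 to 0.01). On the authors' scale it read 0.298 and 0.0203 after IL-17A/F against 0.386 and 0.646. The other end of the ranking held Fyn Y531, the inhibitory tail tyrosine of a Src-family kinase, with a log2 difference of 0.19 (SE 0.090, 95% CI -0.03 to 0.41). CCR7 S356/7, a chemokine receptor, had a difference of 0.32 (SE 0.16) and BATF T48, an AP-1 family factor, of 0.30 (SE 0.15). None of the 300 peptides passed the test.

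The JAK-STAT and interferon list had the lowest mean difference of the 11 lists, -0.04, over all 30 peptides, with 13 of 24 measured peptides lower, 11 higher and 0 past the test. STAT4 S721 had a log2 difference of -0.23 (SE 0.14) and STAT4 Y693 of -0.17, and STAT3 S727 was below background on all arrays. The list's unadjusted camera p was 0.0333, its adjusted p from camera in limma 0.366, and its unadjusted p 0.0957 with an estimated correlation. Its median difference was -0.0086. The tyrosine kinase and adaptor list counted 19 higher and 16 lower of 35 measured peptides. There PXN Y31 (paxillin), a focal adhesion scaffold, had a difference of 0.33 (SE 0.22), IGF1R Y1166 of 0.23 (SE 0.16), VEGFR-1 Y1169 (FLT1) of 0.18 (SE 0.12) and FAK Y397 (PTK2) of -0.23 (SE 0.14). The IGF1R Y1166 difference was -0.11 in replicate 1 and 0.57 in replicate 2. Src S74 was above background on 1 unstimulated array and on neither IL-17A/F array, and its direction rests on that array. The difference ranged from -0.57 to 0.0050 as each array was left out and was 0.019 without background correction.

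The NF-κB list counted 7 higher and 10 lower of 17 measured peptides, with a camera p of 0.750. IRAK1 T209, in a kinase downstream of IL-1 and Toll-like receptors, had a difference of 0.18 (SE 0.12), with -0.0046 and 0.37 in the 2 replicates. NFkB-p65 S536 had a difference of -0.11 (SE 0.15) after IL-17A/F, and IKK-beta Y199 of -0.01 (SE 0.11). In the MAP kinase list, with 16 higher and 10 lower of 26 measured, ASK1 S83 (MAP3K5) had a difference of -0.33 (SE 0.21). The ASK1 S83 difference was 0.030 and -0.69 in the 2 replicates and ranged from -0.57 to -0.11 as each array was left out. The cytoskeleton list counted 4 higher of 8 measured, and RAC1 S71, a small GTPase of actin remodelling, had a difference of -0.23 (SE 0.13). The RAC1 S71 difference was -0.00071 in replicate 1 and -0.46 in replicate 2. p47phox S370 (NCF1), an organizer of the phagocyte NADPH oxidase, had a difference of -0.42 (SE 0.24), from 1.46 and 1.32 on the authors' scale against 1.38 and 2.34. BCAP Y281 had a difference of 0.21 (SE 0.11), CD28 Y206/9, a T-cell receptor co-stimulator, of 0.36 (SE 0.24), and 1 of 2 Akt1 peptides printed without a site of -0.14 (SE 0.090). The CD28 Y206/9 difference was -0.020 and 0.74 in the 2 replicates and ranged from 0.14 to 0.59 as each array was left out. PKCB S15/T16 was below background on all arrays. The PI3K and AKT list counted 7 higher of 11 measured, the PKC, PKA and calcium list 2 of 10, the apoptosis list 7 of 13, the co-activator list 7 of 15, the lymphocyte receptor list 2 of 6 and the cell cycle list 1 of 5, with 0 past the test in each.

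In limma, 0 peptides passed an adjusted p of 0.05 after IL-17A/F, and the smallest adjusted p was 0.999. At an unadjusted p of 0.05 there were 0 peptides, at 0.06 there was 1, and 0 passed the study's cutoffs. With the replicate number as a term in the model, 4 peptides had an unadjusted limma p below 0.05. Without normalization between arrays, 295 peptides passed limma's adjusted p, all lower, with a median log2 shift of -0.59 over all peptides. On the authors' relative values 1 peptide passed the study's cutoffs, CTNNB1 S675, which lay at the floor on both IL-17A/F arrays. With 0.1 added to all values it did not pass and SEK1 S80, higher after IL-17A/F, did; both were singled out after their values were seen.

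The cytokines were also compared directly. Relative to IL-17A/F, cells given IL-32γ had lower values at NFkB-p65 S536 (log2 difference -0.48, SE 0.15), Elk-1 T417 (-0.35, SE 0.15), NFkB-p105 S337 (-0.20, SE 0.081) and Cbl Y371 (-0.23, SE 0.096). B-Raf T598, in the activation loop of a kinase above ERK, had a difference of -0.25 (SE 0.092). Values were higher at IKK-beta Y199 (0.32, SE 0.11), RAC1 S71 (0.33, SE 0.13), 1 of 2 FLT3 peptides, that with the lower-numbered tyrosines (0.34, SE 0.15), CD45 S999/02/03 (0.28, SE 0.12), STMN1 S15 (0.22, SE 0.090), a microtubule regulator, and IL-10R-A Y496 (0.16, SE 0.077). For RAC1 S71, IL-17A/F replicate 2 read 0.187 on the authors' scale against 0.901 in IL-17A/F replicate 1. Jun S63 was below background on all arrays. None passed limma's adjusted p, whose smallest value was 0.995. At an unadjusted limma p under 0.05 there were 5 peptides where chance gives 15, and 10 with the replicate number as a term. By the study's cutoffs 0 passed. On the authors' relative values 3 passed them, all lower after IL-32γ: NFkB-p105 S337, NFkB-p65 S536 and FGFR1 Y154, the last at the floor on 1 IL-32γ array and singled out after its values were seen.

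The JAK-STAT and interferon list counted 14 higher and 10 lower of 24 measured peptides after IL-32γ relative to IL-17A/F, with an unadjusted camera p of 0.0391, an adjusted p of 0.431 from camera in limma and an unadjusted p of 0.102 with an estimated correlation. The NF-κB list counted 5 higher and 12 lower of 17 measured, and the MAP kinase list 11 and 16 of 27. The co-activator list counted 10 higher of 15 measured, the tyrosine kinase list 18 of 35, the PI3K and AKT list 6 of 11, the PKC, PKA and calcium list 4 of 10, the apoptosis list 4 of 13, the cytoskeleton list 3 of 8, the lymphocyte receptor list 3 of 6 and the cell cycle list 5 of 5. In each of the 11 lists 0 peptides passed. Without background correction, camera gave adjusted p below 0.05 for 3 lists, the NF-κB list (lower) among them. Without IL-17A/F replicate 1, it did so for 2 lists, the JAK-STAT list (higher) among them.

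Whether both cytokines moved the same peptides was asked across peptides, which are not independent replicates. The log2 differences of IL-32γ and IL-17A/F from the shared unstimulated arrays had a Pearson r of 0.43 and a Spearman rho of 0.43. Unchanged groups were simulated against a shared simulated control, with noise drawn independently for each peptide and array. They gave a Pearson r of 0.50 (95% range 0.36 to 0.62). The covariance was 0.00495, below the simulated 95% range of 0.00515 to 0.0116 (mean 0.0079), a range that shared deviations could widen. With no array shared, which also pairs the cytokines across different experiments, r was -0.38 and -0.22. Leaving out unstimulated replicate 1 gave 0.78 and IL-32γ replicate 2 gave 0.20. Among the peptides taken by rank in both comparisons, BCAP Y281 had higher values (0.24 and 0.21). Both differences use the same unstimulated arrays, which read 0.835 in replicate 1 and 0.416 in replicate 2 on the authors' scale. In replicate 1 the differences were 0.12 for IL-32γ and 0.0074 for IL-17A/F, so a shared response cannot be told from a shared low control. With 0 peptides past the study's cutoffs in either comparison, their overlap could not be assessed.

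Within experiments, the log2 differences of replicate 1 and of replicate 2 had a Pearson r of -0.29 for IL-32γ and -0.30 for IL-17A/F across the 300 peptides. This was outside the 95% range of -0.19 to 0.19 from simulated unchanged arrays. Noise there was drawn independently for each peptide and array, so shared deviations could widen that range. Without background correction, r was 0.0025 for IL-32γ and -0.40 for IL-17A/F. NFkB-p65 S536 was lower in both experiments after IL-32γ (-0.82 and -0.34), as was NFkB-p105 S337 (-0.22 and -0.41).

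**Figure D3:**
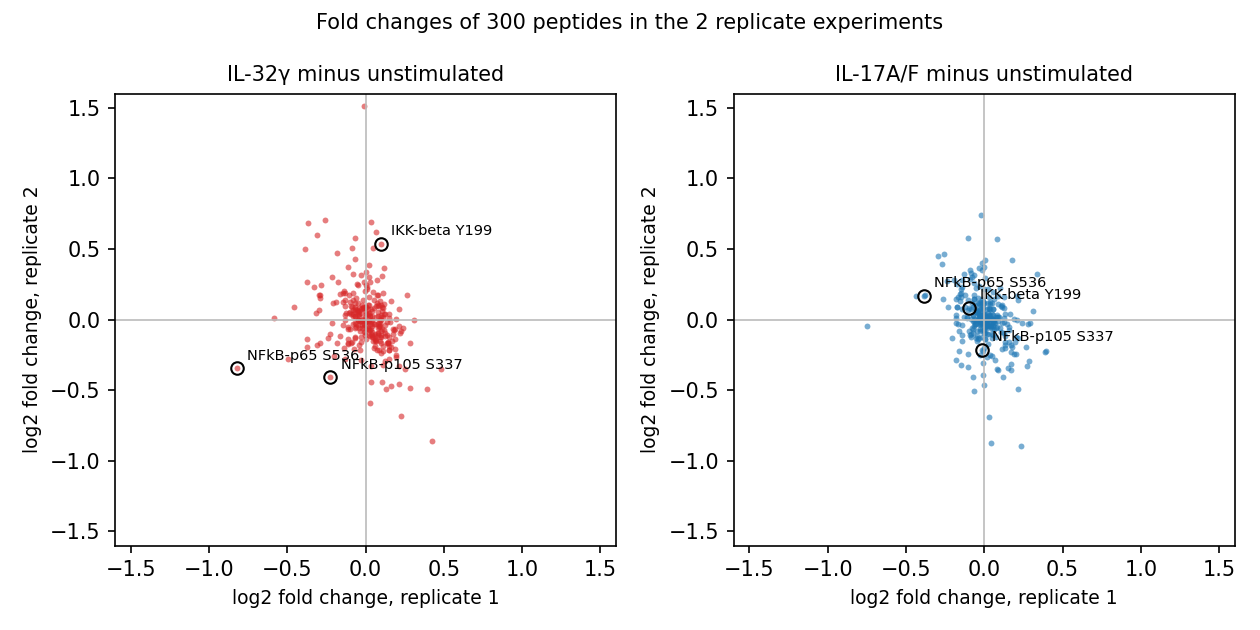
Each point is one of 300 peptides, with its log2 fold change against unstimulated cells in replicate 1 on the x axis and in replicate 2 on the y axis, for IL-32γ and IL-17A/F. The correlations are -0.29 and -0.30, and the circled NFkB-p65 S536 lies at -0.82 and -0.34 for IL-32γ.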

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

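The alternatives that normalize the parts of an array separately, that add 0.1 to the authors' values, that keep peptides above the floor and that treat spots of the authors' scaling as samples were chosen after seeing the data. Over 27 alternatives, 240 of 301 values that answer a comparison stayed the same by a set rule. Counts had to stay equal or within 1.5 times of the main value. Correlations had to keep their sign and move by less than their SD over left-out arrays. Where that SD was lacking, a set fraction of the simulated range was used. Of 1293 values of named peptides, 1248 kept their sign and side of the adjusted p threshold. Of the other values of named peptides, 24 changed sign and 21 came to pass the adjusted p. No values were computed for 11 named differences of peptides below background on every array of both groups. As each array was left out, 38 of the 53 named differences moved by over 1.5 times in at least 1 fit. NFkB-p65 S536 was lower after IL-32γ than in unstimulated cells in 26 of 26 settings, main included, with log2 differences from -0.72 to -0.45 and adjusted p from limma from 0.119 to 1. NFkB-p105 S337 was lower in 25 of 25. Settings that change only the variance model, the block or the use of spots as samples keep each difference of the main setting. Leaving out an IL-17A/F array alters these differences only through the normalization. Both peptides came from the top of the ranking on these arrays, so these counts are not independent support. The counts for named peptides above include such fixed values too. Signal over background limits what the arrays can show, since 74 peptides exceeded background on no array. With the replicate block, 0 peptides and 0 lists passed in each comparison, so it changed no call. In this balanced design the block leaves every difference as it was, so the correlation of fold changes had to stay at 0.43. The block changes the error: 8, 4 and 10 peptides had an unadjusted limma p below 0.05, against 4, 0 and 5 without it. Same-numbered arrays had deviations that correlated at 0.18, 0.02 and 0.40. With 1 of these under 0.1 the correlations alone do not show that the numbers pair the samples. Local background had its highest median at spot position 3 on all 3 replicate 1 arrays and at position 2 on all 3 replicate 2 arrays, so the numbers go with a layout of background. The correlation between experiments was not recomputed for the fits that change only the model, the block or the left-out array, and the overlap not for pairs without shared arrays, where a single array gives no p. For every value that follows, the cause was not tested unless stated.

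In the order IL-32γ against unstimulated, IL-17A/F against unstimulated and IL-32γ against IL-17A/F, the study's cutoffs passed 9, 0 and 9 peptides without background correction and 3, 4 and 4 with background subtracted at floor 1. They passed 1, 0 and 0 with offset 10, 1, 0 and 1 with cyclic loess, and 3, 153 and 17 without normalization. They passed 3, 1 and 3 on the authors' values, 1, 1 and 3 on those plus 0.1 (for IL-17A/F another peptide than on the values themselves), and 1, 1 and 3 on those above the floor on all arrays. They passed 4, 1 and 6 with spots of the authors' scaling as samples, and 8, 1 and 5 without background correction and with parts normalized separately. Peptides past limma's adjusted p numbered 1 for IL-32γ against IL-17A/F with background subtracted at floor 1 (IL-10R-A Y496). Without normalization they numbered 295, all lower, for IL-17A/F and 4 for IL-32γ against IL-17A/F. The median log2 shift of all peptides was then -0.24, -0.59 and 0.36, and named values are relative to it. Lists past camera's adjusted p numbered 2, 0 and 3 without background correction, 4, 0 and 3 with parts normalized separately as well, and 0, 1 and 0 without normalization. The overlap of study-cutoff peptides was 3 without normalization, 1 on the authors' values and 1 without background correction and with parts normalized separately.

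The correlation between the cytokines turned to -0.38 and -0.22 when no array was shared. This removes the shared controls but also pairs arrays of different experiments. Across experiments IL-32γ alone gave -0.29 and IL-17A/F alone -0.30, so values below 0 also arose within each cytokine. All of these values set unstimulated replicate 1 against unstimulated replicate 2. A difference between those arrays is therefore not excluded as the source of the turn in sign. The correlation between experiments for IL-32γ was 0.0025 without background correction, 0.030 with parts normalized separately as well, and -0.19 with dim peptides left out. For IL-17A/F it was -0.40 without background correction, -0.13 with median scaling or no normalization, and -0.14 on the authors' values above the floor on all arrays.

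Signs turned for these log2 differences. Without background correction, IL-17A/F against unstimulated gave VEGFR-1 Y1169 -0.070, PXN Y31 -0.052, Src S74 0.019 and p300 S1834 -0.055, and IL-32γ against IL-17A/F gave DAPK1 S308 0.11. With parts normalized separately as well, p300 S1834 was -0.012 and DAPK1 S308 0.040. With background subtracted at floor 1, BCAP Y281 was -1.32 after IL-17A/F, and between cytokines DAPK1 S308 was 0.62 and p300 S1834 -0.073. With the median of spots, EphA1 Y781 was -0.024, IGF1R Y1166 -0.031 and p300 S1834 -0.099 between cytokines. p300 S1834 between cytokines was also -0.32 on the authors' values, -0.20 on those plus 0.1, -0.83 with spots of their scaling as samples and -0.045 with parts normalized separately. BCAP Y281 after IL-17A/F was -0.14 with those spots as samples, and Cbl Y371 between cytokines was 0.0097 with median scaling.

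With each array left out in turn, the study's cutoffs passed 1 to 3 peptides for IL-32γ, 0 to 2 for IL-17A/F and 0 to 1 between cytokines. For IL-32γ the peptide was NFkB-p65 S536 without unstimulated replicate 2, IL-32γ replicate 2 or either IL-17A/F array. Without unstimulated replicate 1 there were 3, Pyk2 Y402 and PIK3R1 S608/7 among them, and without IL-32γ replicate 1 there were 2, HSP27 among them. Lists past camera's adjusted p between cytokines numbered 0 to 2, the 2 without IL-17A/F replicate 1. The correlation between cytokines ranged from 0.20 to 0.78 and the overlap from 0 to 1. Ranges that crossed 0 were -0.027 to 0.12 (DAPK1 S308) for IL-32γ. For IL-17A/F they were -0.57 to 0.0050 (Src S74) and -0.020 to 0.22 (DAPK1 S308). Between cytokines they were -0.17 to 0.068 (DAPK1 S308) and -0.10 to 0.11 (p300 S1834). A lone array was assumed to vary like the other groups.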

Other observations

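The peptide with the largest fold after IL-32γ, HSP27 (HSPB1, 1 peptide), a small heat shock protein phosphorylated downstream of p38, rested on 1 array. On the authors' scale it read 1.92 on IL-32γ replicate 2, 0.0986 on unstimulated replicate 2 and the floor of 0.01 on the other arrays. Its log2 difference from unstimulated cells was 0.75 with a limma SE of 0.55 and an unadjusted limma p of 0.222, and it was singled out after its values were seen. The 2 printed copies of Akt1 without a site differed in log2 difference by 0.11 after IL-32γ and 0.19 after IL-17A/F, and those of PLCB1 S887 by 0.033 and 0.063. Across peptides the median SD was 0.149 between the spots of an array and 0.103 between the arrays of a group.

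The tests of the NF-κB peptides were set before their results were seen. The peptides themselves were taken from the top of the ranking by t. The tests of the correlation between experiments and of the lower unnormalized signal were chosen after their results were seen. NFkB-p65 S536 and NFkB-p105 S337 were lower after IL-32γ in both experiments. In 12 of 12 comparisons of spots at the same position the signal was lower after IL-32γ, so the differences did not rest on single spots. Peptides picked for low values tend to have lower spots, so this count says nothing about chance. Chance among 300 peptides stays open: in a share of 0.91 of 200 simulated unchanged data sets the smallest p was as small as the one observed. A response of the signal at NF-κB peptides to IL-32γ within 15 min is the biological explanation that the design names. It stays open as a hypothesis.

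The log2 differences of the 2 experiments correlated below 0 for both cytokines. With the main background correction, the mean correlation stayed at -0.257 after each part was normalized on its own. That argues against brightness differences between the 3 parts of an array as the whole cause in that setting. Without background correction the IL-32γ correlation was 0.0025, and 0.030 with parts normalized separately as well. There the test cannot decide for IL-32γ, since its correlation was near 0 before the parts were normalized. A difference that lies in the unstimulated arrays may account for the correlations below 0. IL-32γ minus IL-17A/F, which uses none of these arrays, gave 0.0055 between experiments. Arrays exchanged between groups within experiment 2 cannot be told apart from this: 5 of the 6 arrangements, the labelled one included, correlated with experiment 1 at least as highly as the labelled one, which gave -0.20. 1 arrangement was lower (-0.21) and the highest other gave 0.19, but 6 arrangements are too few for a share under 0.05. No biological explanation was tested.

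Before normalization, net signal was lower on the IL-17A/F arrays, at 0.654 and 0.636 of the same-numbered unstimulated arrays; on the IL-32γ arrays it was at 0.702 and 0.923, with background at 0.639 and 1.03. If stain or scanner gain of the whole slide were the source, local background would change by the same ratio. On the IL-17A/F arrays it was at 0.699 in replicate 1 and 1.08 in replicate 2, which gave net over background ratios of 0.936 and 0.59. In replicate 1 net signal and background were thus lower together after both cytokines, and in replicate 2 net signal alone was lower after IL-17A/F. The arrays differ, so gain and lower phosphorylation of the printed peptides as a whole after IL-17A/F cannot be told apart here. The latter is a hypothesis that was not tested.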
